A study of Mus musculus with 3 samples.

How the data were processed

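Single-cell RNA sequencing with 10x Genomics 5' chemistry was analysed in 3 libraries of sorted mouse regulatory T cells (Tregs, CD4 T cells that express the transcription factor Foxp3 and restrain immune responses). All mice carried a FoxP3GFP reporter, received subcutaneous medroxyprogesterone acetate, a progestin, and were sampled on day 7 after an intravaginal inoculation. The LN mock library came from vaginal-draining lymph nodes after mock infection, the LN HSV-2 library from the same lymph nodes after infection with herpes simplex virus 2, and the VT HSV-2 library from infected vaginal tissue. Cells were sorted as live, CD45-positive, CD4-positive and FoxP3-positive, and the VT HSV-2 cells also as negative for an intravenous CD45.2 label, which marks cells in the blood vessels. There was 1 library per group, and whether cells of several mice were pooled is not given in the sources used here.

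The deposited values are raw counts of unique molecular identifiers (UMIs) per gene and cell barcode, made with Cell Ranger 3.0.2 per the file headers and aligned to GRCm38 per the submitters' processing notes. No normalization had been applied. Each file held 27998 genes, and the lowest total of any barcode was 500 UMIs in the LN mock library and 501 in the others. Gene symbols and Ensembl identifiers were taken from the files, and 27645 of them matched a gene of the GENCODE M21 annotation, from which GRCm38 positions were taken. The usage of T cell receptor V genes, planned as a description, was not analysed here because the feature tables used hold 0 T cell receptor or immunoglobulin segment genes.

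Barcodes with fewer than 300 detected genes or more than 10% mitochondrial UMIs were left out, which left 2132 of 2189 barcodes in LN mock, 1520 of 1570 in LN HSV-2 and 350 of 359 in VT HSV-2. Doublets were called in each library with Scrublet as implemented in scanpy 1.11.5, with an expected rate of 0.8% per 1000 barcodes. The automatic threshold called 7 barcodes in LN mock, 13 in LN HSV-2 and 45 in VT HSV-2. The last is 12.9% of the VT HSV-2 barcodes, far above the 0.28% the caller was told to expect, and keeping called doublets was one of the alternatives. The remaining barcodes of the 3 libraries were log-normalized to 10000 UMIs, and 2000 variable genes without mitochondrial and ribosomal protein genes were scaled and reduced to 30 principal components. A graph of 15 neighbours was partitioned with the Leiden algorithm (igraph 0.11.9) at a resolution of 1 into 14 clusters, with no batch correction.

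Clusters were named by fixed markers, at least 3 of which had to be among the 50 genes with the highest fold over the other cells. Clusters 4 and 5 were resting Treg-like (markers include Ccr7 and Tcf7), clusters 0 and 11 effector Treg-like (Icos, Klrg1 and Gzmb), clusters 2 and 13 interferon-responding (Isg15 and Ifit1), and cluster 12 cycling (Mki67 and Top2a). A further 6 clusters stayed unnamed. The name of cluster 2 is uncertain: it had 4 such markers among its first 50 genes and 0 among its first 10. At a resolution of 1.5 a cluster with the same leading genes, such as Gbp2 and Tgtp1, was named resting Treg-like. Cluster 1, led by markers of other cell types, held 54, 76 and 106 barcodes of LN mock, LN HSV-2 and VT HSV-2 with a median of 598 UMIs and was removed. The kept cells numbered 2071 in LN mock, 1431 in LN HSV-2 and 199 in VT HSV-2, with 9205023, 7939361 and 1088838 UMIs. Their median depth was 3552, 4456 and 4585 UMIs per cell. Most clusters were filled mainly by 1 library, so cluster sizes were not compared.

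UMIs were summed over the kept cells of each library and expressed as CPM, counts per 1000000 UMIs of the library, with exact Poisson 95% intervals. The libraries were compared by the ratio of CPM with an exact conditional (Clopper-Pearson) 95% interval, and shares of cells carry exact binomial intervals. These intervals cover counting error only. Cells are not replicates, so there is no test between conditions and no p-value. A size rule counted genes with at least 100 UMIs in both libraries together and a CPM ratio of at least 2 in either direction. For each list of genes, the median log2 CPM ratio was taken over members with at least 20 UMIs in both libraries together, after adding 0.5 UMI to each sum. Its 95% range came from 1000 Poisson redraws, and its percentile from 10000 random lists of the same size matched on mean expression, as a description of these libraries. A list member was counted as higher or lower when its CPM ratio was at least 1.5 in that direction and its interval excluded 1. Shares of cells with a UMI were given as measured and after every cell was thinned to 1900 UMIs.

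The comparisons, the size rule, the markers, the cell filters, the alternatives except 3 and 30 gene lists were chosen before the data were examined. The 3 alternatives added after the data were seen left out barcodes under 1000 UMIs, barcodes shared by the lymph node libraries, and the cell with the most UMIs. Of these lists, 18 cover Treg identity, resting T cells, effector Treg activation, tissue residency, tissue egress, tissue repair, Th1-type Tregs, type I interferon, interferon gamma, cell cycle, chemokine receptors and integrins, suppressor molecules, T cell receptor signals, NF-kB, immediate early and dissociation stress, glycolysis, oxidative phosphorylation and lipid synthesis. The other 12 hold markers of B, plasma, myeloid, dendritic, neutrophil, CD8 T, NK and innate lymphoid, gamma delta T, conventional CD4 T, epithelial, stromal and red blood cells. Named genes were the 12 higher and 12 lower per comparison whose interval bound lay farthest from 1, among genes with at least 100 UMIs and a ratio of at least 1.5, without mitochondrial, ribosomal protein, receptor segment and unnamed genes. Up to 4 members per list by the same bound were added, with Foxp3, Cd4 and Il2ra as a check of the labels. Genes outside this rule are said to have been chosen after their values were seen. Some genes that the rule names are not reported here. VT HSV-2 differs from LN mock in tissue and infection together, so those libraries are set side by side as levels only.

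The procedure was tested on simulated counts drawn from the real libraries' means and totals, with 200 genes changed by known folds. These simulated sums followed the Poisson model that the intervals assume and held no variation between cells. They check the computation, not how the intervals or the size rule hold for genes clumped in few cells. For LN HSV-2 over LN mock, with 7844 genes, the intervals held the true ratio for 95.6% of genes, the size rule took all genes simulated at 3-fold or 4-fold higher and at 0.25 of their level, and it took 67.4% of those at 0.5 and 0% of unchanged genes. For VT HSV-2 over LN HSV-2, with 6307 genes, the intervals held 95.7%, and the size rule took 98.0% of genes at 0.25 of their level, 49.0% of those at 0.5 and 0.589% of unchanged genes. Alternatives covered the barcodes used, doublets, the mitochondrial limit, cells with a Foxp3 UMI, cycling cells, clustering resolution, classes of cells, median-of-ratios size factors, totals without the most abundant genes, equal weight per cell, thinning, and UMI minimums. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9.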

Results

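Regulatory T cells (Tregs) were profiled by droplet-based single-cell RNA sequencing from 3 sources on day 7: vaginal-draining lymph nodes of mock-infected mice (LN mock), the same lymph nodes after intravaginal infection with herpes simplex virus 2 (LN HSV-2), and infected vaginal tissue (VT HSV-2). The title of the series names the question, whether a mucosal virus infection gives Tregs an activated state that differs from tissue residency. There was 1 library per group, with no replicates. The deposited barcodes held 9374996 UMIs in LN mock, 8144663 in LN HSV-2 and 1441370 in VT HSV-2. After filtering, 2071, 1431 and 199 cells remained, with a median of 3552, 4456 and 4585 UMIs per cell. Every ratio below compares a pair of libraries, and the bracketed 95% intervals cover counting error only.

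Genes behind the sort were present in all 3 libraries. Foxp3, the transcription factor that defines Tregs, stood at 88.1 CPM (82.1 to 94.4) in LN mock, 123 (115 to 131) in LN HSV-2 and 139 (117 to 163) in VT HSV-2. Cd4 was level across the libraries, at 116, 123 and 128 CPM. Il2ra, the high-affinity chain of the interleukin-2 receptor, stood at 251, 322 and 452 CPM. A Foxp3 UMI was found in 28.1% of LN mock, 38.6% of LN HSV-2 and 41.7% of VT HSV-2 cells, and in 15.5%, 20.5% and 18.1% after thinning to 1900 UMIs, which left out 179, 72 and 22 cells. In the removed cluster of other cell types, with a median of 598 UMIs, 0.847% of 236 barcodes had one. At 500 UMIs per barcode, where the 2 can be set side by side, the shares were 4.93%, 5.80% and 7.04% in the kept cells and 0.424% in that cluster. A Cd4 UMI was found at that depth in 5.70%, 6.08% and 6.53% of kept cells and in 6.36% of that cluster, so Cd4 does not set the kept cells apart from it. Cd3e, a T cell gene chosen after its values were seen, was found in 36.6%, 36.4% and 35.2% of kept cells and in 26.7% of that cluster. The cluster thus holds T cell RNA and is no clean reference for other cell types.

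The first comparison, LN HSV-2 over LN mock, asks what infection of the vagina goes with in Tregs of the draining lymph node. Interferon-induced genes were more abundant in the infected library, and so were 3 genes of cytotoxic granules, Gzmb, Gzma and Prf1, while the granule-associated protease gene Ctsw was less abundant. Gzmb, which encodes the granule protease granzyme B, stood at 1078 CPM against 38.8, and Ly6a, an interferon-inducible surface protein, at 1111 CPM against 141. Of 21 genes that T cell receptor signals induce, 8 were less abundant and 1 more, the former including the nuclear receptors Nr4a2 and Nr4a3 and the NF-kB subunit Rel. Of the effector Treg activation genes, about as many were lower as higher.

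Of 7886 genes with at least 100 UMIs, 150 were at least 2-fold higher in LN HSV-2 and 167 at least 2-fold lower, and 96.0% lay within 2-fold. Gzmb (ENSMUSG00000015437, chromosome 14, 56258838 to 56262260, minus strand, protein-coding) was 27.8-fold higher (25.0 to 31.0), with UMIs in 292 cells against 68. Its share of cells was 20.4% against 3.28%, or 16.2% against 2.06% after thinning. In resting Treg-like cells, where little is expected, it was 2.72% and 0.265%, or 1.43% and 0.282% thinned, at median depths of 3878 and 3527 UMIs. The removed cluster of other cell types had the opposite order, 23.7% of 76 LN HSV-2 barcodes against 42.6% of 54 LN mock barcodes. This order is no measure of background. In 31 pairs a shallow LN mock barcode shared its sequence with a deep LN HSV-2 barcode, and 0 of these shallow barcodes were kept. How many of them lie in the removed cluster was not determined. Gzma, a second granzyme, was 114-fold higher (31.0 to 945) on 196 UMIs against 2, or 38.7-fold with the cluster of other cell types kept. Il12rb2, the signalling chain of the interleukin-12 receptor, was 70.7-fold higher (19.2 to 591) on 122 against 2, or 19.5-fold after thinning. Ly6a (ENSMUSG00000075602, chromosome 15, 74994877 to 74998031, minus strand, protein-coding) was 7.89-fold higher (7.44 to 8.36). The interferon-induced membrane protein gene Ifitm3 (ENSMUSG00000025492, chromosome 7, 141009586 to 141010770, minus strand, protein-coding) was 12.1-fold higher (9.62 to 15.5). Its neighbour Ifitm1 was 264-fold higher (47.0 to 10486), but 7 cells against 1 carried it and the ratio was 110 without the cell that held 58.3% of the UMIs and 20.1 with the cluster of other cell types kept. The remaining genes named as higher were Sv2c (12.7), Ston1 (9.76, or 19.3 in cells with a Foxp3 UMI), Plac8 (8.37, or 5.0 after thinning), Elovl6, a fatty acid elongase (5.57), Gimap7, a small immune GTPase (5.28), and the interferon-induced GTPase gene Gbp2 at 218 CPM against 43.7.

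Among the genes lower in LN HSV-2, Nr4a2 (ENSMUSG00000026826, chromosome 2, 57106830 to 57124003, minus strand, protein-coding) stood at 92.3 CPM against 317, a ratio of 0.291 (0.268 to 0.315). Dusp14, a phosphatase that dampens T cell receptor signalling, had a ratio of 0.135 (0.108 to 0.166), and Penk, the precursor of opioid peptides, of 0.242 (0.212 to 0.275). The protease gene Ctsw was at 0.197, the regulator of G-protein signalling Rgs16 at 0.222, the transcription factor Klf4 at 0.294 and the splicing-related Rsrp1 at 0.304. Among the genes listed in this paragraph, the lowest ratios belonged to genes of modest abundance, Ptpn5 at 0.0945 (0.0461 to 0.174) and C2cd4b at 0.109 (0.0594 to 0.185). Nav2 (0.174), Cpd (0.206) and Gsta4 (0.247) completed the named genes.

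Both interferon lists were higher. Of 31 measured type I interferon response genes, 24 were at least 1.5-fold higher, 0 lower and 7 neither, with a median log2 ratio of 1.08 (0.94 to 1.23), above every one of 10000 matched random lists (percentile 100). Rtp4 was 3.49-fold and Ifit1, an inhibitor of viral translation, 3.42-fold higher. Of 29 interferon gamma response genes, 18 were higher, 0 lower and 11 neither, with a median of 0.84 (0.72 to 0.95) and percentile 100. Besides Gbp2, the GTPase genes Tgtp1 (4.22-fold), Tgtp2 (3.36-fold) and Ifi47 (2.90-fold) led them, but Tgtp1 and Tgtp2 are near-identical copies, as the Gbp genes partly are, and their single values are uncertain. Of 17 Th1-type Treg genes, 10 were higher and 4 lower, with a median of 0.82 (0.66 to 0.97) and percentile 100. Beside Gzma and Il12rb2, the Th1-associated chemokine receptor gene Cxcr3 was 4.20-fold higher, while Ctsw was lower. Thinning every cell left a median of 0.30 for this list.

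Lists of resting and recirculating T cells leaned upward. The resting list had 5 of 16 genes higher and 1 lower, with a median of 0.38 and percentile 100; Il7r, a survival receptor, was 2.36-fold, the chromatin organizer Satb1 2.21-fold and Bcl2 1.67-fold higher. The egress list had 4 of 11 higher and 0 lower (median 0.45, percentile 99.97), with Ly6c2 5.26-fold higher, a near-identical copy of Ly6c1 and so uncertain. Its ratio lay between 3.89 and 13.1 over the alternatives run on all classes of cells. Glycolysis genes had 2 of 16 higher and 0 lower (median 0.37, percentile 99.99), with Tpi1 1.55-fold higher.

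The T cell receptor signal list was lower, with 8 of 21 genes lower and 1 higher and a median of -0.53 (-0.57 to -0.37), below every random list (percentile 0). Nr4a3 had a ratio of 0.335, the activation marker Cd83 of 0.341 and Rel of 0.401. The tissue residency list had 0 of 15 genes higher and 5 lower, Nr4a2 and Rgs2 (0.545) among the latter. Its median was -0.24 (-0.32 to -0.06), with percentile 2.18, but 0.00731 in cells with a Foxp3 UMI. The tissue repair list had 0 of 13 higher and 4 lower (median -0.38, percentile 0.15), with the alarmin receptor gene Il1rl1 at 0.443, the nuclear receptor Rora at 0.552 and the growth factor Areg at 0.599. Immediate early and dissociation stress genes went both ways, 3 higher and 7 lower of 23 (median -0.22, percentile 0.34), with Atf3 at 0.307 but Jun at 1.96 and the heat-shock gene Hspa1a, a near-identical copy of Hspa1b, at 2.31. Lipid synthesis genes had 0 of 21 higher and 5 lower (median -0.13, percentile 13.2), with Insig1 at 0.580.

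Other lists held members that moved apart. The effector Treg activation list had 5 of 27 genes higher, 6 lower and 16 neither, with a median of 0.08 (0.03 to 0.14) and percentile 87.1, and of -0.19 when every cell was thinned to the same depth. Gzmb was higher, while Cd83, the adhesion receptor Cd44 (0.381) and the adenosine-producing Nt5e (0.423) were lower. Suppressor molecule genes split 5 higher and 6 lower of 19, with Prf1, the granule pore protein, 5.51-fold higher on 38 UMIs against 8 and the integrin chain Itgb8 at 0.285; the median was -0.03 and the mean 0.51, and the median lay between -0.36 and 0.21 over the alternatives run on all classes of cells. Chemokine receptor and integrin genes split 7 and 7 of 23 (median -0.14, percentile 4.87), with the oxysterol receptor Gpr183 3.45-fold higher. Treg identity genes had 2 higher and 3 lower of 15 (median 0.04, mean -0.09), with Gpr83 2.15-fold and Socs2 1.81-fold higher and Nrp1 at 0.365 and the integrin chain Itgae at 0.532. Cell cycle genes had 0 higher and 1 lower of 30, Stmn1 at 0.655 (median 0.01, mean -0.01, but -0.49 without the barcodes that both lymph node libraries share), NF-kB targets 2 higher and 3 lower of 21, with Bcl3 at 1.72 (median -0.08), and oxidative phosphorylation genes 0 and 0 of 32 (median -0.02).

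Of the markers of other cell types, conventional CD4 T cell markers had 4 of 6 measured genes lower and 0 higher (median -0.74), with Bcl6, the transcription factor of follicular T cells, at 0.338. CD8 T cell markers had 3 of 3 higher (median 1.36). Cd8b1 stood at 21.8 CPM in 124 cells against 14.2 CPM in 106, a ratio of 1.53 (1.21 to 1.94), Cd8a at 5.92 CPM in 9 cells against 2.28 CPM in 5, and Eomes was found in 14 cells against 6. Medians were 0.19 for B cell markers (4 measured), -0.26 for myeloid (5), 0.21 for NK and innate lymphoid (3) and 0.01 for epithelial markers (3, mean -0.16). A single gene was measured for each of 4 further lists: -2.63 for plasma cells, -0.27 for dendritic cells, 1.52 for neutrophils and 0.16 for stromal cells. The gamma delta T and red blood cell lists had 0 measured genes.

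Within both classes of cells the interferon lists stayed higher, while the ranges of the T cell receptor signal and egress lists reached past 0. The resting and effector classes hold 377 and 207 of 2071 LN mock cells and 367 and 318 of 1431 LN HSV-2 cells, so their medians do not cover the libraries. The T cell receptor signal genes Egr2, Egr1 and Nr4a1 were among the leading genes of cluster 9, which is in neither class. Cluster 4 held 320 of 377 resting Treg-like cells of LN mock and cluster 5 held 268 of 367 of LN HSV-2, so the class is split along the libraries; cluster 0 likewise held 194 of 207 effector Treg-like cells of LN mock and cluster 11 held 275 of 318 of LN HSV-2. The type I interferon median was 0.91 within resting and 0.73 within effector cells, and the interferon gamma median 0.82 and 0.53. Ly6a was 5.16-fold higher within resting and 4.02-fold within effector cells, and Gzmb 23.7-fold higher within effector cells. The Th1-type median was 1.08 (0.80 to 1.56) within effector and 0.15 (-0.28 to 0.58) within resting cells. Of the CD8 T cell markers within effector cells, Cd8a had 27 UMIs against 0 and Cd8b1 a ratio of 1.74 (0.981 to 3.28). The T cell receptor signal median was -0.17 (-0.42 to 0.03) within resting cells, with 2 genes higher and 6 lower of 19, and -0.12 (-0.26 to 0.04) within effector cells, with 4 higher and 2 lower of 19. The egress median was 0.15 (-0.08 to 0.33) within resting and 0.01 (-0.13 to 0.18) within effector cells, and the resting list median -0.01 and 0.01. The residency median was 0.01 within resting and -0.35 within effector cells, the tissue repair median -0.36 and -0.13 and the stress median -0.03 and -0.52. The glycolysis median was 0.17 within resting and 0.52 within effector cells. The lipid synthesis median was -0.72 (-0.999 to -0.19) within resting cells, with 0 of 15 genes higher, 5 lower and percentile 0, and -0.18 (-0.42 to 0.08) within effector cells. Within resting cells Satb1 (0.777), Cd83 (1.33) and Nt5e (1.18), and within effector cells Gpr83 (0.826), lay on the other side of 1.

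The second comparison, VT HSV-2 over LN HSV-2, asks how Tregs inside the infected tissue differ from those in its draining lymph node. Of 27 effector Treg activation genes, 22 were more abundant in the tissue library, among them the suppressive cytokine gene Il10 and the inhibitory receptor gene Klrg1. Of 13 tissue residency genes, 4 were more abundant there, among them the chemokine receptor gene Cxcr6. Ccr7 and Klf2, which direct T cells into and out of lymph nodes, were less abundant.

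Of 6318 genes with at least 100 UMIs, 146 were at least 2-fold higher in VT HSV-2 and 226 at least 2-fold lower, and 94.1% lay within 2-fold. With totals that leave out the most abundant genes, the median of all genes shifted by -0.15 on the log2 scale and the split became 90 higher and 343 lower. With the scaling unchanged but the interval required to lie beyond 1.5-fold, 157 were higher and 84 lower. The balance of higher and lower genes thus depends on both the scaling and the rule. Il10 (ENSMUSG00000016529, chromosome 1, 131019845 to 131024974, plus strand, protein-coding) was 8.54-fold higher (6.22 to 11.7), at 81.7 CPM against 9.57. A UMI of Il10 was found in 19.6% of VT HSV-2 cells against 2.66%, or 11.3% against 1.25% after thinning, and in 0 of 24 and 0 of 367 resting Treg-like cells, at median depths of 3376 and 3878 UMIs. Klrg1 (ENSMUSG00000030114, chromosome 6, 122270596 to 122282882, minus strand, protein-coding) was 5.78-fold higher (4.92 to 6.77), and found in 23.6% of cells against 5.87%, or 18.1% against 3.24% thinned, with 0 of 24 and 1 of 367 resting Treg-like cells. The protease inhibitor genes Ctla2a (14.7-fold, 12.8 to 17.0) and Ctla2b (14.1-fold) were higher too, but are near-identical copies. So were Fgl2, a secreted suppressor molecule (6.42-fold), the calcium-binding S100a4 (4.82-fold), Ltb4r1, a leukotriene B4 receptor (7.70-fold), Cxcr6 (7.96-fold, 23 cells against 29) and Phkg1 (5.72-fold, 15 cells against 32). The ratio of Ltb4r1 lay between 5.52 and 15.4 over the alternatives run on all classes of cells. Few cells carried the remaining ones: the chemokine gene Ccl4 was 53.6-fold higher with 11 cells against 5, and 35.2-fold without the cell with the most UMIs. Ccl3 was 30.3-fold higher with 5 cells against 6, and 12.8-fold without 1 cell, and Ifitm1 9.31-fold with 8 cells against 7.

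Of the genes lower in VT HSV-2, the lymph node homing receptor Ccr7 (ENSMUSG00000037944, chromosome 11, 99144196 to 99155077, minus strand, protein-coding) stood at 269 CPM against 1065, a ratio of 0.253 (0.224 to 0.284). Klf2, which drives genes of recirculation, had a ratio of 0.426 (0.360 to 0.502), the inducible heat-shock gene Hspa1a of 0.161 (0.0800 to 0.291) and Gclm, an enzyme subunit of glutathione synthesis, of 0.418. Penk (ENSMUSG00000045573, chromosome 4, 4133531 to 4138819, minus strand, protein-coding) had 2 UMIs in VT HSV-2 against 283, a ratio of 0.0515 (0.00621 to 0.188). Lad1 with 1 UMI had a ratio of 0.0708 (0.00178 to 0.403) and Plagl1 with 3 UMIs of 0.164 (0.0335 to 0.491). The others were Ppp3r1, a calcineurin subunit (0.249), Ifngr2, a chain of the interferon gamma receptor (0.308), Igfbp4 (0.344, but 0.796 in cells with a Foxp3 UMI), Nsg2 (0.351) and Cd74 (0.366). Cd74, the invariant chain of antigen-presenting cells, came out at 1.17 when the removed cluster of other cell types was kept.

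The effector Treg activation list had 22 of 27 measured genes higher, 1 lower and 4 neither, with a median log2 ratio of 1.06 (0.89 to 1.14) and percentile 100 among matched random lists. Beside Il10, Klrg1 and S100a4, the higher genes included S100a6 (4.16-fold) and Gzmb (2.97-fold, 2.85 to 3.09), and Cd83 (0.376) was the exception. The tissue residency list had 4 of 13 higher, 1 lower and 8 neither, with a median of 0.36 (0.23 to 0.46) and percentile 97.8. Its higher members included Cxcr6, the transcription factor Prdm1 (2.73-fold) and Litaf (2.03-fold), and the phosphatase gene Inpp4b was lower (0.512). Cd69 had a ratio of 1.30 (1.14 to 1.48) and Itgae of 0.813 (0.546 to 1.17), a difference not detectable at this depth; this pair was chosen after their values were seen. The resting list had 0 of 16 higher and 7 lower (median -0.51, percentile 0), with Bcl2 at 0.416. The egress list had 1 higher and 4 lower of 11 (median -0.46, percentile 0.05, but -0.05 in cells with a Foxp3 UMI). In it the transcription factor Tcf7 had a ratio of 0.384, between 0.167 and 0.504 over the alternatives run on all classes of cells. The 1 higher egress gene was Ly6c2, at 1.55 without the cell with the most UMIs.

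**Figure D1:**
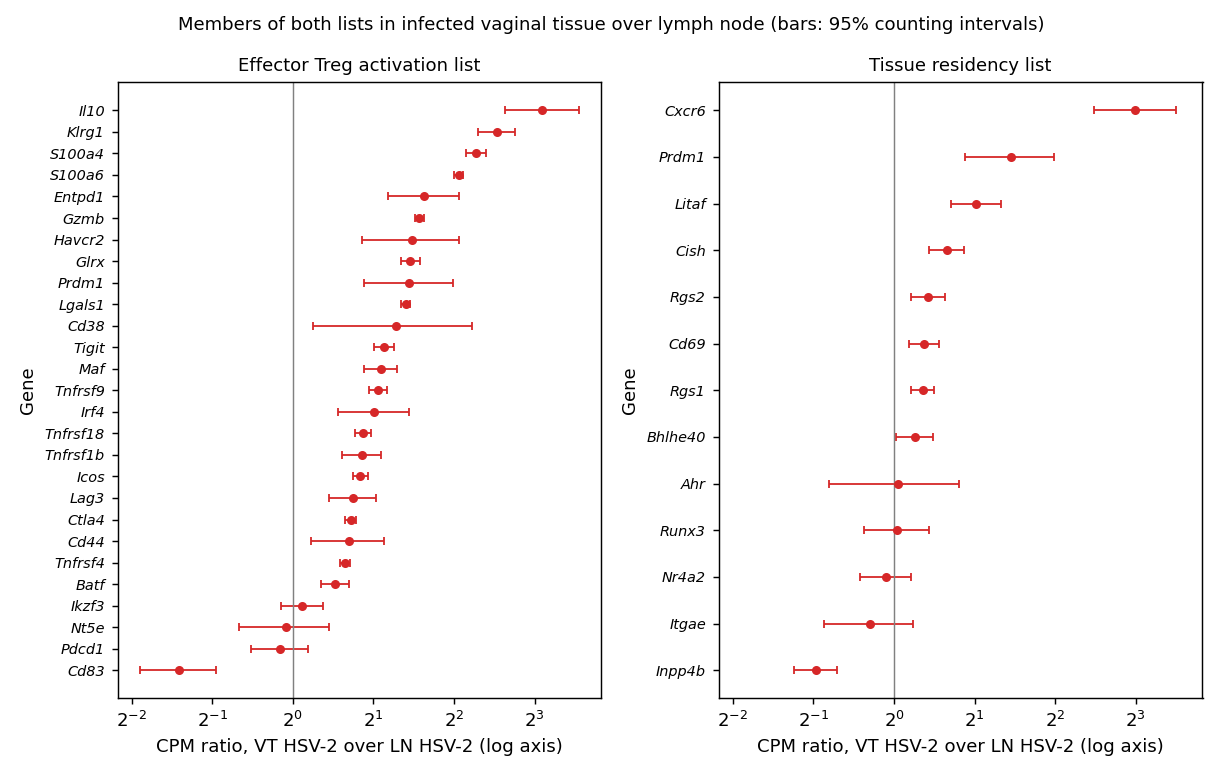
CPM ratio of VT HSV-2 over LN HSV-2 on a log axis for each measured member of the effector Treg activation list (left) and the tissue residency list (right), with 95% counting intervals as bars and a line at equal levels. Of the effector genes 22 of 27 were at least 1.5-fold higher, from Il10 at 8.54 down, and of the residency genes 4 of 13, led by Cxcr6 at 7.96.

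Suppressor molecule genes were higher as a group, 10 of 19 with 1 lower (median 0.72, percentile 100), and so were the Th1-type genes, 12 of 17 with 2 lower (median 1.22, percentile 100). The latter included the Th1 master regulator Tbx21 (4.33-fold), the chemokine gene Ccl5 (4.45-fold), the granule gene Nkg7 (3.56-fold) and Ctsw (4.67-fold). Tissue repair genes had 5 of 13 higher and 2 lower (median 0.50, percentile 99.8), with Areg 2.91-fold higher (2.63 to 3.23), but 1.57-fold in cells with a Foxp3 UMI. Of the lower genes 1, Tff1, had 0 UMIs in VT HSV-2 and all 32 of LN HSV-2 in a single barcode. Of the chemokine receptor and integrin genes 9 of 23 were higher and 1 lower (median 0.24, percentile 94.3), among them Ccr2 (2.78-fold) and Cxcr3 (2.66-fold). Treg identity genes had 5 higher and 1 lower of 15 (median 0.17, percentile 61.4), with Socs2 (2.87-fold), Capg (2.55-fold) and the costimulatory receptor Tnfrsf18 (1.83-fold) higher and Gpr83 (0.342) lower. The interferon lists were only slightly higher: type I had 6 of 30 higher and 0 lower (median 0.34, percentile 99.7), led by Isg20 (2.39-fold), and interferon gamma 3 of 29 higher and 0 lower (median 0.27, percentile 97.0), led by Irf1 (2.07-fold).

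Among the remaining lists, stress genes had a lower median and the others medians between -0.02 and 0.29. Random lists matched to the effector list had a median of 0.13 in this comparison, and those matched to the oxidative phosphorylation list 0.18, so small positive medians carry little. T cell receptor signal genes had 6 of 21 higher, with the costimulatory receptor Tnfrsf9 at 2.09 and the immediate early gene Egr1 at 2.34, and 3 lower (median 0.17, percentile 70.35). Stress genes split 5 and 5 of 23 (median -0.31, percentile 0.01), with Egr1 among the higher and Hspa1a among the lower. Medians were 0.29 for glycolysis (4 of 16 higher), 0.26 for oxidative phosphorylation (1 of 32 higher), 0.06 for cell cycle (7 higher and 3 lower of 30; 0.85 without those shared barcodes), 0.02 for NF-kB targets (3 of 21 higher) and -0.02 for lipid synthesis genes (3 and 3 of 19). Of the markers of other cell types, Cd8a had 0 UMIs in VT HSV-2, against 5.92 CPM in LN HSV-2 on 47 UMIs in 9 cells. By counting error alone this allows up to 2.76 CPM, at least 2.15-fold lower. With UMIs clumped in so few cells, 0 can also arise in the smaller library without a difference. The CD8 T cell list had 2 of 3 lower (median -3.20, or -0.59 with Cd8a and Eomes at that bound). Eomes has the same limit, with 33 UMIs in 14 LN HSV-2 cells. Medians were -0.23 for conventional CD4 T cells (6 measured), 0.52 for myeloid (3), 0.20 for B cell (3, mean -0.18), -0.13 for NK and innate lymphoid (3), 0.20 for epithelial (2), 1.12 for neutrophil (1) and -0.25 for stromal markers (1). No gene was measured for the plasma, dendritic, gamma delta T and red blood cell lists.

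Within the effector Treg-like class, which cluster 11 mostly holds in both libraries (95 of 107 VT HSV-2 and 275 of 318 LN HSV-2 cells), the effector list median was 0.56 (0.45 to 0.66), with 13 of 27 genes higher and 1 lower. The residency median there was 0.33, the resting median -0.48, the suppressor median 0.43, the type I interferon median 0.48 and the egress median -0.43. The Th1-type median was 0.26 (-0.12 to 0.55) and no longer detectably above 0, and the tissue repair median was 0.12 (0.01 to 0.44), percentile 75.65; within cluster 11 alone they were 0.32 (-0.10 to 0.61) and 0.08 (-0.03 to 0.33). Within the 24 resting Treg-like cells of VT HSV-2, 18 of them in cluster 5, the effector median was 0.27 (-0.26 to 0.58) and the residency median -0.10 (-0.77 to 0.32), so no difference was detectable there. The VT HSV-2 library was also sorted by an intravenous label that the lymph node libraries were not, and tissue, sort and library cannot be separated in this comparison.

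**Figure D2:**
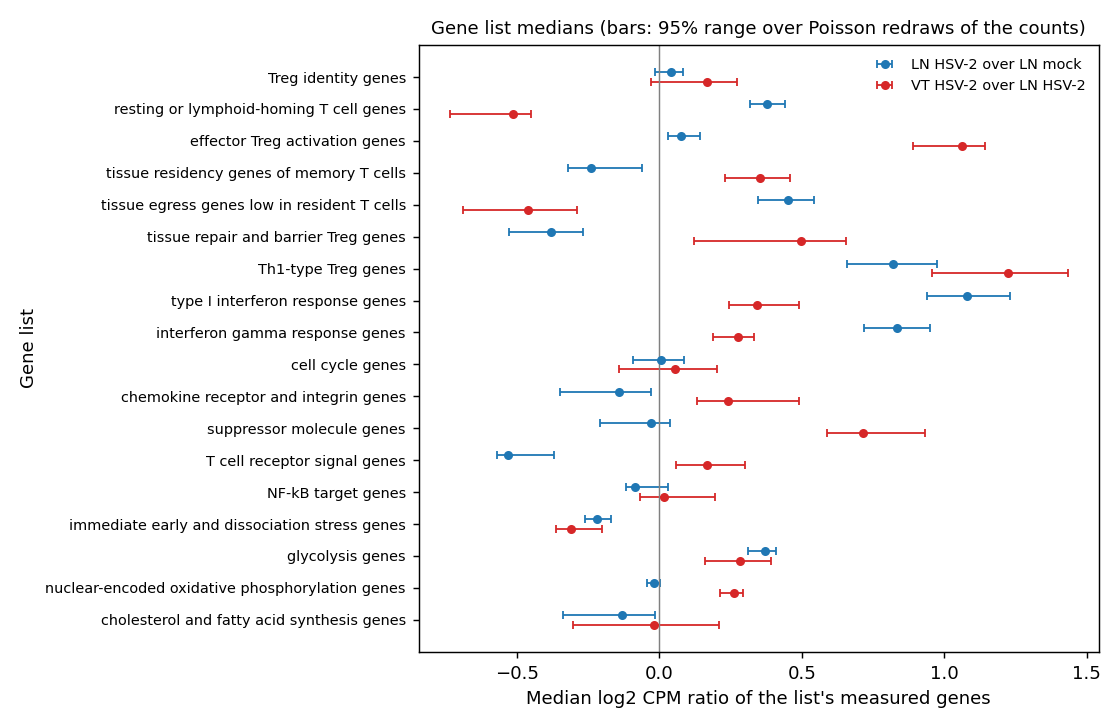
Median log2 CPM ratio of each of 18 gene lists for LN HSV-2 over LN mock (blue) and VT HSV-2 over LN HSV-2 (red), with the 95% range over Poisson redraws of the counts as bars. The interferon lists lie farther right in the lymph node comparison (1.08 and 0.84) and the effector list in the tissue comparison (1.06 against 0.08).

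Set side by side, the 3 libraries showed different orders for different genes. Gzmb stood at 38.8 CPM in LN mock, 1078 in LN HSV-2 and 3200 in VT HSV-2, and Ly6a at 141, 1111 and 2340. Cxcr3 followed the same order at 18.1, 76.2 and 203 CPM. Il10 was near level in both lymph node libraries, at 11.7 and 9.57 CPM, and stood at 81.7 in the tissue, as did Klrg1 at 38.0, 44.8 and 259. Areg was lowest in the infected lymph node, with 271 CPM in LN mock, 162 in LN HSV-2 and 472 in VT HSV-2, and so was Ctsw with 81.7, 16.1 and 75.3. Cd83 stood at 294, 100.3 and 37.7 CPM and Itgae at 67.9, 36.1 and 29.4.

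**Figure D3:**
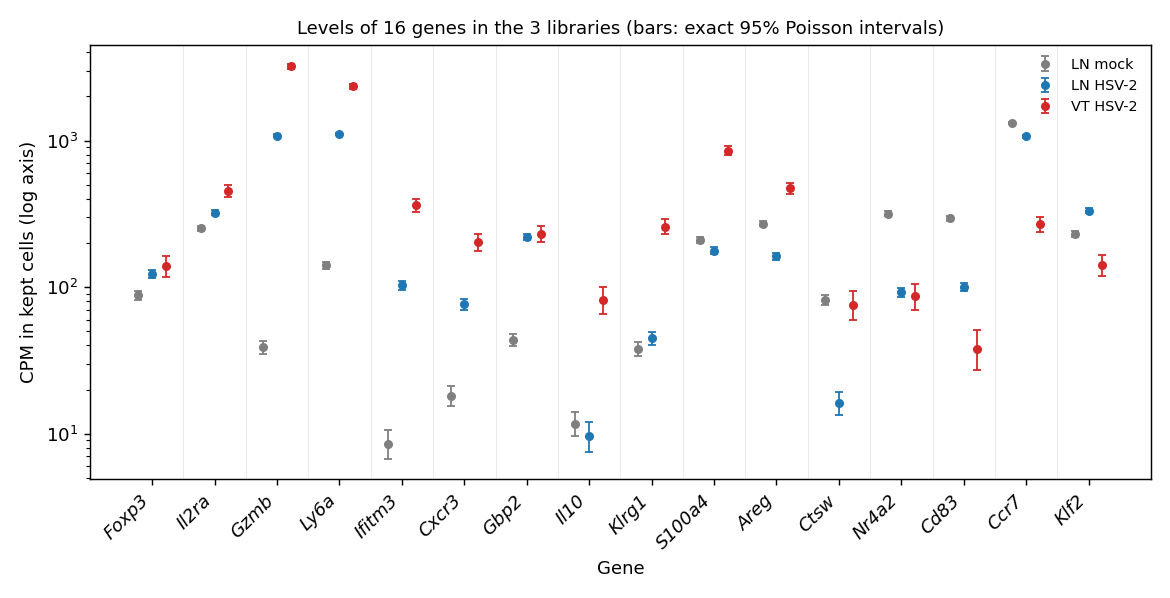
CPM on a log axis of 16 genes in the kept cells of LN mock (grey), LN HSV-2 (blue) and VT HSV-2 (red), with exact 95% Poisson intervals as bars. Gzmb spans 38.8 to 3200 CPM across the libraries, while Foxp3 lies between 88.1 and 139 CPM.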

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

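Of the tests in this part, the number of shared barcodes given by chance was chosen only after the result was seen, while the test of partners was written down before.

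The deposited LN mock and LN HSV-2 barcodes had 62 sequences in common, while VT HSV-2 had 1 in common with LN mock and 0 with LN HSV-2. Chance at the rate of that sharing would give 2.55 (0.0645 to 14.2) between the lymph node libraries, so chance alone was excluded. Of the 62 pairs, 47 joined a deep barcode of 12031 to 39463 UMIs with a shallow one of 505 to 1204, which held a median of 3.18% of the deep barcode's UMIs (2.66% to 4.79%). If molecules of 1 library had been counted under the sample index of the other, the shallow barcode's genes should match its own partner best, and this held in 47 of 47 pairs, with a median of 146 candidates each. This result fits index swapping, and no biological explanation was tested.

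Of the remaining pairs, 13 were shallow in both libraries and 2 were deep in both. The deep member came from LN HSV-2 in 31 and from LN mock in 16 of the unequal pairs, and 0 of their shallow members were among the kept cells. Of barcodes with more than 20000 UMIs, 9 of 13 in LN mock and 19 of 21 in LN HSV-2 were shared. Leaving out the shared barcodes thus removed mainly deep kept cells, from 1431 to 1397 in LN HSV-2 and from 2071 to 2053 in LN mock. The effector list median of LN HSV-2 over LN mock was then -0.03 instead of 0.08. This shift is no measure of index swapping.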

How the results depend on the processing

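Of the alternatives below, leaving out barcodes shared by the lymph node libraries was chosen only after the data were seen, as were leaving out barcodes under 1000 UMIs and leaving out the cell with the most UMIs; all other alternatives were fixed before. The planned description of T cell receptor V gene usage was not run, since the feature tables used hold no such genes. The ratio of each named gene in LN HSV-2 over LN mock stayed inside its counting interval in 908 of its pairings with an alternative. It shifted beyond that interval in 145 and crossed 1 in 5. For VT HSV-2 over LN HSV-2 the numbers were 715, 135 and 8. Crossings were counted only for genes at least 1.5-fold apart with an interval that excludes 1. Others were not counted: Foxp3 lay between 0.984 and 1.40 in the first comparison, and Cd4 between 0.768 and 1.06 in the second. The 0.984 was that of cells with a Foxp3 UMI, a filter on Foxp3 itself, so it does not bear on the Foxp3 difference. The cell cycle median lay between -0.49 and 0.04 for LN HSV-2 over LN mock and between -0.20 and 0.85 for VT HSV-2 over LN HSV-2, so no direction holds for it. Its values of -0.49 and 0.85 were reached without the shared barcodes, which drops most of the deepest lymph node cells. No direction holds either for the suppressor median of LN HSV-2 over LN mock, which was -0.36 with every cell weighted alike and 0.21 in cells with a Foxp3 UMI. The egress median of VT HSV-2 over LN HSV-2 lay between -0.61 and -0.05, the latter in cells with a Foxp3 UMI. The cause of the shifts was not tested unless stated.

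For LN HSV-2 over LN mock, the type I interferon median stayed between 0.85 and 1.12, the interferon gamma median between 0.71 and 0.88 and the T cell receptor signal median between -0.56 and -0.31 under all alternatives other than single classes of cells. The 150 genes at least 2-fold higher became 62 within resting Treg-like cells and 84 after thinning, and the 167 lower became 59 within resting and 54 within effector Treg-like cells, where fewer UMIs reach the minimum. With a minimum of 30 UMIs 286 were higher and 369 lower, and with none 1543 and 2183, as more genes enter. The effector list median of 0.08 became 0.38 in cells with a Foxp3 UMI, 0.0179 without cycling clusters, 0.0281 within resting and 0.0148 within effector Treg-like cells. Its sign turned to -0.0349 without the shared barcodes, -0.14 with every cell weighted alike and -0.19 after thinning, so no direction holds for this list. The residency median of -0.24 turned to 0.00731 in cells with a Foxp3 UMI and to 0.0111 within resting Treg-like cells, and was -0.35 within effector Treg-like cells. Within resting Treg-like cells the resting median turned to -0.00670 and the chemokine receptor and integrin median to 0.0889; the latter was 0.00244 with members of any UMI count. The myeloid marker median of -0.26 became 1.61 with all deposited barcodes and 1.76 with the other-cell-type cluster kept. The leading genes of that cluster include myeloid markers such as Lyz2, along with B cell and dendritic cell markers. Gpr83 turned to 0.826 within effector, and Satb1 to 0.777, Cd83 to 1.33 and Nt5e to 1.18 within resting Treg-like cells, and Cd8a to 0.946 in cells with a Foxp3 UMI. Thinning also moved Ifitm3 to 7.44.

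For VT HSV-2 over LN HSV-2, the effector median stayed between 0.89 and 1.20, the Th1-type median between 1.05 and 1.45, the suppressor median between 0.57 and 0.81 and the resting median between -0.66 and -0.43 under all alternatives other than single classes of cells. The 146 genes at least 2-fold higher became 79 in cells with a Foxp3 UMI, 21 within resting and 51 within effector Treg-like cells, 93 after thinning and 220 with every cell weighted alike. The 226 lower became 118 within resting and 83 within effector Treg-like cells, 117 after thinning, and 84 when the interval had to lie beyond 1.5-fold. Under that last rule 157 genes were higher. Totals without the most abundant genes gave 90 higher and 343 lower, a minimum of 30 UMIs 316 and 668, and no minimum 1309 and 3361. The effector median of 1.06 was 0.27 within resting and 0.56 within effector Treg-like cells, 1.20 with equal weights and 1.18 after thinning. The residency median of 0.36 was 0.21 with totals that leave out the most abundant genes and 0.55 after thinning. Within the 24 resting Treg-like cells of VT HSV-2 it turned to -0.10, as did the type I interferon median to -0.16, the chemokine receptor and integrin median to -0.23, the stress median to 0.0947 and the glycolysis median to -0.10. In the same cells Igfbp4 turned to 1.23, Ppp3r1 to 1.06, Cd83 to 1.02, Nkg7 to 0.827, Isg20 to 0.680 and Ctsw to 0, on few UMIs. In cells with a Foxp3 UMI S100a4 moved to 3.01, Areg to 1.57 and Igfbp4 to 0.796, and thinning moved Penk to 0.169 and Ppp3r1 to 0.463. Cd74 turned to 1.06 with all deposited barcodes and 1.17 with the other-cell-type cluster kept.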

Other observations

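In this part, the tests of the effector and interferon lists were chosen only after the results were seen.

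Some genes lay at least 2-fold apart in both comparisons. Of 6314 genes with at least 100 UMIs in both, 19 were higher in LN HSV-2 than in LN mock and higher again in VT HSV-2 than in LN HSV-2, where independent lists would share 3.04. Beside Gzmb, Cxcr3 and Ifitm3 these included Ccr2, the receptor for monocyte-recruiting chemokines. A further 10 were lower at both steps (2.54 for independent lists), among them Cd83, Penk, Bcl6 and Klf4. Another 12 were higher in LN HSV-2 than in LN mock and lower in VT HSV-2 than in LN HSV-2 (4.83), among them Cxcr5, the receptor that leads cells into B cell follicles, Gpr83 and Hspa1a. The last 10 were lower in LN HSV-2 than in either other library (1.60), with the protease gene Ctsw, the interleukin-18 receptor gene Il18r1 and the chemokine gene Cxcl10 among them. The minimum in both comparisons left 135 of the 150 higher but 71 of the 167 lower genes of LN HSV-2 over LN mock. The groups of genes lower in LN HSV-2 are therefore cut by this minimum. The comparisons share the LN HSV-2 library, and part of the excess of genes with opposite directions may come from it. Simulated counts without any difference gave 0 genes in each of the 4 groups, but 0% of unchanged genes pass the size rule in LN HSV-2 over LN mock, so this simulation does not bear on the shared library. These members were chosen after their values were seen.

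The Th1-associated transcription factor Tbx21 stood at 3.26 CPM in LN mock, 8.69 in LN HSV-2 and 37.7 in VT HSV-2. The suppressor gene Fgl2 stood at 15.5, 8.44 and 54.2 CPM, and the tissue marker Cd69 at 179, 191 and 248. Within cluster 11, which effector Treg-like cells of LN HSV-2 and VT HSV-2 both fill, Klrg1 was 4.31-fold, Cxcr6 5.23-fold, Ctsw 6.14-fold, Il10 3.62-fold, Areg 2.94-fold and Gzmb 1.58-fold higher in VT HSV-2.

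The effector list was higher in VT HSV-2 than in LN HSV-2, and 3 explanations were weighed. A larger share of cells in the effector Treg-like clusters did not give the whole difference, since within cluster 11 the median was still 0.59 (0.43 to 0.67, counting error only) against 1.06 in all cells. That share may account for part of the difference, and a different mix of cells inside cluster 11 was not tested. RNA with the profile of the removed VT HSV-2 cluster of other cell types gave 0.370% of the excess of the median gene and at most 1.58%, for Lgals1. This was at the highest level that 10 myeloid markers with 16 UMIs allow, and it argues against RNA of that cluster as the main cause. RNA of cells without those markers, such as other T cells, was not bounded. The cluster also held 0 CPM of Klrg1, Prdm1, Il10 and S100a4, so their share was fixed in advance. A difference in depth was excluded, with a median of 1.18 after thinning. The intravenous label and the dissociation of tissue were not tested.

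The interferon lists were higher in LN HSV-2 than in LN mock, and a restriction to the interferon-responding clusters was excluded, since the type I median outside them was 1.14 (0.89 to 1.22). It lay above 0 in 10 of 11 clusters with enough cells of both libraries, from -0.20 to 1.44, the exception being cluster 2, 1 of the interferon-responding clusters, at -0.20 (-0.37 to 0.19), and the interferon gamma median in 11 of 11. A difference in depth as the whole cause was excluded too, with a median of 0.91 after thinning. No test separates a broad interferon response from another difference between the libraries.

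All 62 UMIs of Sprr2f and all 32 of Tff1, genes of epithelial cells, were in the same LN HSV-2 barcode of 712 UMIs. A shared pair shallow in both libraries also held a kept LN HSV-2 barcode of 712 UMIs, against 507 in LN mock. Whether it is the same barcode was not checked. Of the deposited VT HSV-2 barcodes 32.3% had fewer than 1000 UMIs. The deepest kept cell held 2.12% of the UMIs of VT HSV-2 and 0.43% of those of LN HSV-2.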
